A study of Mus musculus with 4 samples.

How the data were processed

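RNA from sorted effector regulatory T cells of mouse Peyer's patches was sequenced in 4 libraries, 2 labelled wild type and 2 labelled Maf flox, all with a Cre recombinase at Foxp3. Per the labels' protocols, RNA was collected in Trizol, purified on spin columns and made into libraries with an ultra-low input mRNA kit. Per the submitters' processing notes, TopHat2 2.1.1, HTSeq 0.6.1 and edgeR 3.14 were used with genome build mm10; their settings, the annotation and the use of strand are not given in the sources used here. The authors deposited a table of raw counts per gene symbol for the 4 libraries. It had 24061 gene rows and 5 counter summary rows, which were left out of library sizes and tests. The summary rows made up 66.6%, 66.7%, 66.8% and 67.2% of the column totals of the libraries labelled wt 1, wt 2, flox 1 and flox 2. Of the reads that the counter placed on the genome once, 42.3%, 42.1%, 42.1% and 41.8% were assigned to a gene and 57.2%, 57.4%, 57.3% and 57.7% to none. In 27 rows the gene symbol had been turned into a date. These rows were tested but are not named. Of the gene rows, 94.4% had a symbol in the GENCODE annotation of the same genome build, from which coordinates were taken.

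The authors also deposited a filtered table of normalized values (10618 rows), a signal that is never negative and not whole. Each value lies near the raw count times a factor nearly constant within a library, with medians of 1.034, 1.061, 0.882 and 1.033. Pseudo-counts in the sense of classic edgeR, which are counts adjusted to a common library size, were recomputed for these rows from the raw counts under each of the 3 ways to put 4 libraries into 2 groups of 2. With the libraries numbered 1 as 1 group and those numbered 2 as the other, 100% of the 42472 values lay within a relative error of 1e-06 of the deposited ones. With the labelled groups 3.2% did, and with the remaining grouping 3.4%. These values were described and set beside the fit, and no count test was run on them.

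Samples were grouped by genotype as their titles give it, with the replicate number of the title. A separate replicate field of the labels gives 1 for both libraries labelled wt and 2 for both labelled flox, and was not used. Because Maf counts went against the labels of wt 2 and flox 1, libraries are called by their labels and no library was moved to another group. Other groupings of the 4 libraries were fitted only to count called genes under each, and the one by number coincides with the Maf level.

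Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 13022, library sizes were scaled by TMM, and labelled flox was compared with labelled wt by glmQLFit (robust) and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error was the log2 fold change divided by the root of F. The biological coefficient of variation was 0.273. CPM values use TMM library sizes. With 2 libraries against 2, an exact permutation test of a single gene cannot go below a two-sided p of 0.333, so none was run. A count floor of 3 corresponds to 0.146, 0.148, 0.123 and 0.145 CPM in the 4 libraries. Intervals of counts are exact Poisson intervals, and ratios of counts have exact binomial ones, at 95%.

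Gene lists were fixed before the data were examined, 26 in all. They cover the MAF family, core and effector regulatory T cell genes, type 17, follicular, type 2 and tissue, type 1, resting, homing, T cell receptor response, immediate early and heat shock, cell cycle, interferon, cytokine and inhibitory receptor genes. They also cover markers of B, CD8 T and natural killer, conventional CD4 T, myeloid, innate lymphoid, epithelial, stromal and red cells, sex-linked genes, and neighbours of Maf and of Foxp3. Lists with at least 4 tested members were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation and by fry. Genes named in the text were Maf, 16 fixed genes, up to 12 called genes per direction with a mean log2 CPM of at least 3 and separate groups (leaving out predicted genes, pseudogenes and receptor segments, of which 1 was called), and up to 4 members of each list by smallest unadjusted p. Because fewer than 10 genes passed, the 10 with the smallest p were named too. Some genes that the rule names are not reported here.

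Alternatives were DESeq2 1.42.0, other scalings and filters, other tests of edgeR, limma-voom, a minimum fold of 1.5, a replicate block and leaving out each library. Before use, the tests were checked on simulated counts for this comparison, drawn from the real means, library sizes and dispersions with 200 changed genes (12737 genes run). The dispersions were estimated with the labelled groups, so they include the difference in Maf level within each label and what goes with it. The rates below hold for that spread only. The filter kept 98 of the genes changed 2-fold, 95 of those changed 4-fold and 12544 unchanged ones. The quasi-likelihood test called 34.7%, 69.5% and 23 of them, respectively, so that 18.7% of its 123 calls were unchanged genes at a threshold of 0.05. Unchanged genes made up 27.8% of 158 calls by the likelihood ratio test, 28.8% of 160 by the exact test, 28.3% of 166 by DESeq2 and 13.3% of 98 by limma-voom. With 20 simulated lists, camera called the 1 raised list with its preset correlation and 0 others, and 0 with an estimated correlation. The simulated genes varied independently, so this check does not cover lists whose members vary together.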

Results

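Regulatory T cells of the effector type were sorted from the Peyer's patches of mice, the lymphoid follicles of the small intestine, as CD4-positive, FoxP3-positive cells that lacked CD62L. The mice were 13 weeks old and carried a Cre recombinase with a yellow fluorescent reporter at the Foxp3 locus, which acts in regulatory T cells. The labels give a backcross generation of 5 for every library. According to the labels, 2 libraries came from mice with intact Maf alleles (labelled wt 1 and wt 2) and 2 from mice whose Maf alleles were both floxed (labelled flox 1 and flox 2). About 40000 cells went into each RNA sample. The question was which transcripts of these cells depend on c-Maf, a basic leucine zipper transcription factor encoded by Maf. Gene totals were 21148345 counts in the library labelled wt 1, 19368745 in wt 2, 24687897 in flox 1 and 20809399 in flox 2. The labels do not say whether libraries of 1 group came from separate animals, so the p-values measure only the spread between these samples, part of which may be technical. That spread also holds the difference in Maf level within each label, given below. For genes that go with the Maf level, such as Il10, this widens the spread against which the labels are compared. Poisson and ratio intervals (95%) cover counting error only.

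Maf did not follow the labels. It had 3071 counts in the library labelled wt 1 (95% interval 2960 to 3180) and 2975 in the library labelled flox 1 (2870 to 3080), but 40 in the library labelled wt 2 (28.6 to 54.5) and 15 in the library labelled flox 2 (8.4 to 24.7). Scaled to library size as CPM these were 149, 122, 1.98 and 0.725. The library labelled wt 1 was thus 75.5 times as high as the library labelled wt 2 (interval 55.3 to 106), and the library labelled flox 1 was 168 times as high as flox 2 (102 to 301). By label, Maf averaged 75.6 ± 104 CPM in wt and 61.3 ± 85.7 in flox (SD, n = 2), with a log2 fold change of -0.30 (SE 2.63, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1). The sign changed when the library labelled wt 1 or the library labelled flox 2 was left out, where the log2 fold change was 4.95 and 0.69. Maf lies on chromosome 8 at 115682942 to 115707794, minus strand (mm10 coordinates). The labels of wt 2 and flox 1 were therefore at odds with the targeted gene. Libraries are named by their labels throughout, and every direction given for flox against wt is a direction between labels, not between measured Maf levels. Values of the 4 libraries are listed below in the order labelled wt 1, labelled wt 2, labelled flox 1 and labelled flox 2.

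Several genes of intestinal and follicular regulatory T cells differed between libraries of 1 label. Il10, an anti-inflammatory cytokine, had 429, 24.5, 385 and 26.8 CPM, with ratios of 17.5 within wt (16 to 19.2) and 14.3 within flox (13.2 to 15.7). Il21, a cytokine of follicular T cells, had 19, 0.346, 14.5 and 0.967 CPM, and Il17a, the cytokine of type 17 cells, had 3.5, 0.593, 4.59 and 0.919. Among the genes of follicular T cells, Cxcr5, the receptor that guides cells into follicles, had 202, 65.9, 181 and 89.4 CPM. The follicular transcription factor Bcl6 had 260, 111, 253 and 162, Pdcd1 had 720, 312, 676 and 441, and Icos had 1180, 608, 1320 and 858. The ratio within a label was smaller for these 4 genes, 1.95 to 3.06 within wt and 1.53 to 2.03 within flox. Prdm1, which encodes Blimp-1, had 134, 88, 118 and 83.2 CPM, and Ctla4 had 3340, 1630, 3340 and 2080.

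Foxp3, the gene that defines the lineage, was near 100 CPM in every library (93.8, 104, 91 and 104). Il2ra had 454, 503, 401 and 510 CPM and Ikzf2, which encodes Helios, had 190, 174, 209 and 215. Gata3, a transcription factor of type 2 and tissue regulatory T cells, had 457, 463, 391 and 728 CPM. Tbx21, which encodes T-bet, had 14.7, 15.8, 19.6 and 22.2, and Ccr6 had 67, 95.7, 76.1 and 57.8. By label none of the 15 fixed genes given here passed the edgeR quasi-likelihood test (adjusted p = 1 for each), and 1 of them, Tbx21, had an unadjusted p under 0.05 (0.0468). For Il10 the log2 fold change of labelled flox over labelled wt was -0.14 (SE 1.87), so that the spread between libraries of 1 label exceeded the difference between labels.

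**Figure D1:**
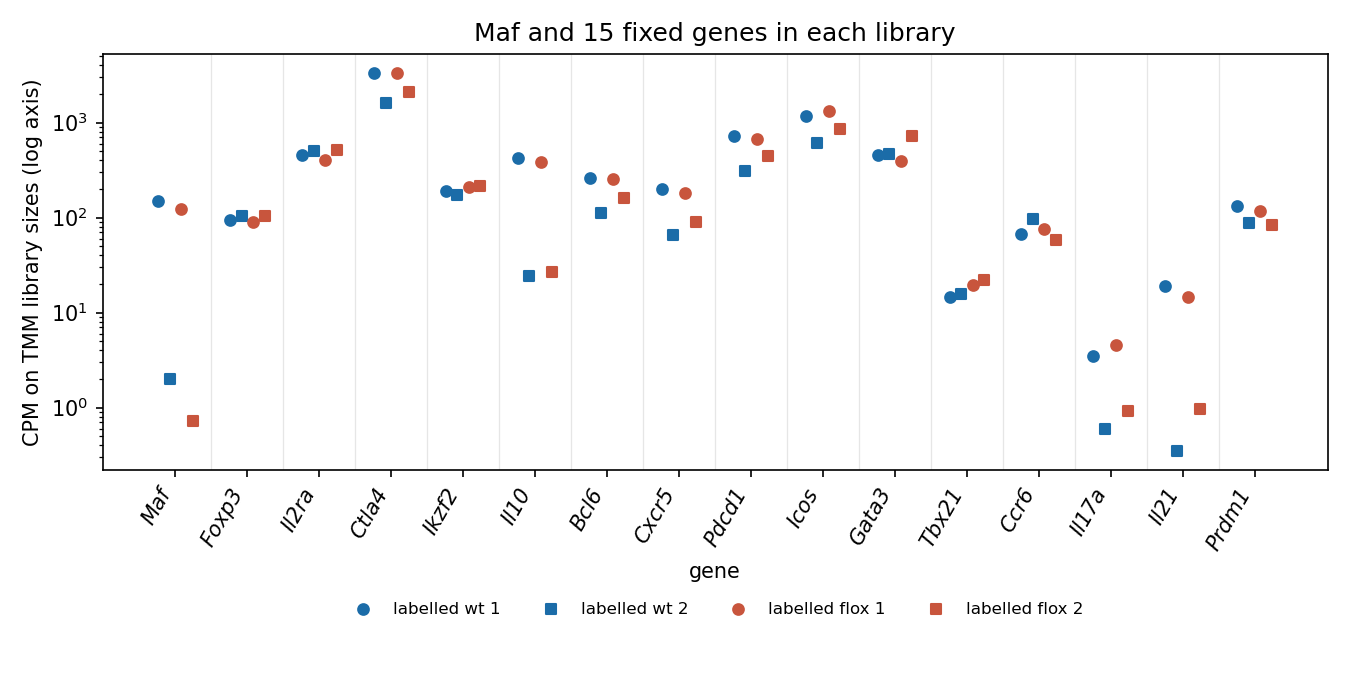
Level of Maf and of 15 fixed genes (x axis) in each library, as CPM on TMM library sizes on a log axis; blue symbols are libraries labelled wt and red ones libraries labelled flox, circles are number 1 and squares number 2, with 1 point per library. Maf lies at 149 and 122 CPM in the libraries labelled wt 1 and flox 1 and at 1.98 and 0.725 in those labelled wt 2 and flox 2.

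Across the 13022 tested genes, the closest libraries carried the same number, not the same label. The Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.976 between the libraries labelled wt 1 and flox 1 and 0.974 between wt 2 and flox 2. It was 0.962 between the libraries labelled wt 1 and wt 2 and 0.964 between flox 1 and flox 2. The first principal component held 48.1% of the variance, with scores of 42.7 and 24.6 for the libraries labelled wt 1 and flox 1 and of -29.5 and -37.8 for wt 2 and flox 2. Both libraries of 1 label lay above both of the other for 3515 genes (27%), where chance gives 33.3%.

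**Figure D2:**
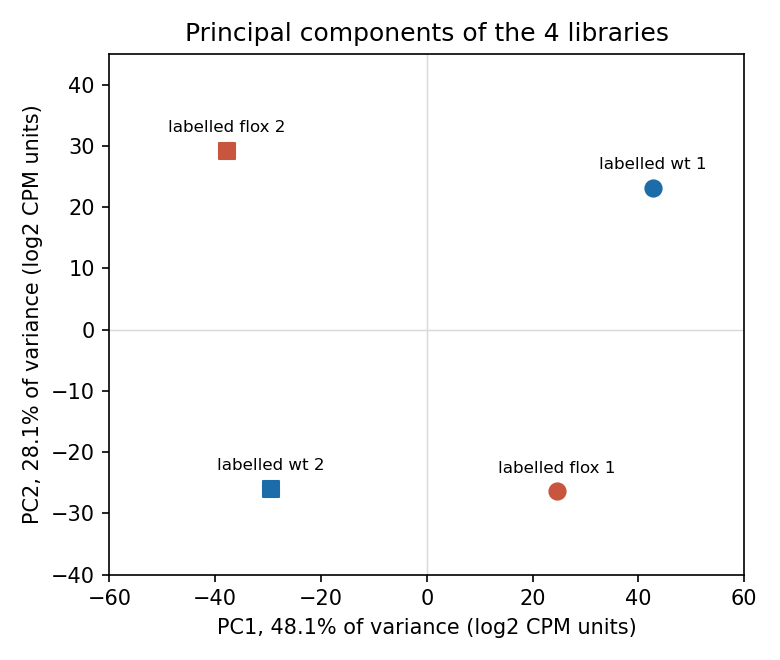
Scores of the 4 libraries on the first principal component (x axis, 48.1% of the variance) and the second (y axis, 28.1%) of log2 CPM over the tested genes; blue is labelled wt, red labelled flox, circles number 1 and squares number 2. The libraries labelled wt 1 and flox 1 lie on the positive side of the first component and those labelled wt 2 and flox 2 on the negative side.

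By label, 1 of the 13022 genes passed the edgeR quasi-likelihood test (adjusted p under 0.05), higher in labelled flox, and 0 were lower; 258 genes (1.98%) had an unadjusted p under 0.05. The gene was Gm8615, a transcribed processed pseudogene on chromosome 5 (149155108 to 149156209) and the gene with the smallest p. It had 1 count in each library labelled wt, and 440 and 454 counts in the libraries labelled flox 1 and flox 2. The ratio of its level was 404 (interval 112 to 3340) and its adjusted p was 0.0322. Its sequence matches that of Gnpda1, which encodes a glucosamine-6-phosphate deaminase, at 99.07% of 753 aligned bases, so that the division of reads between both genes is uncertain. Gnpda1, on chromosome 18 at 38327535 to 38339003 and named after its values were seen, had 43.6, 58, 20.3 and 26.7 CPM. By label it did not pass edgeR's quasi-likelihood test (log2 fold change -1.11, SE 0.21, adjusted p = 1) and was called lower in labelled flox by DESeq2 (adjusted p = 0.0331). With the counts of both genes summed, levels were 43.6, 58, 38.3 and 48.7 CPM and no gene passed. The Gm8615 call was lost when any 1 library was left out, which leaves 1 library in a label. Its counts of 1 in each library labelled wt and of 440 and 454 in flox stay apart whichever library is removed. The lost call thus says little about the size of the difference. DESeq2 called 12 genes, 9 of them higher in labelled flox, the edgeR likelihood ratio test 12 and its exact test 6, while limma-voom called 0 with 262 at an unadjusted p under 0.05. On simulated counts with 12544 unchanged genes, DESeq2 called 47 of these, the likelihood ratio test 44 and the exact test 46, against 23 by the quasi-likelihood test.

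The genes next in order of p had separate levels by label without passing the quasi-likelihood test. Kcnn2, a calcium-activated potassium channel on chromosome 18, had 0 counts in both libraries labelled wt and 9.38 and 8.51 CPM in those labelled flox, at least 60.8-fold higher than a floor of 3 counts per library (adjusted p = 0.579). Sh3rf2, on the same chromosome, had 0.34, 0.247, 3.52 and 5.32 CPM. Camk2b, a subunit of a calmodulin-dependent kinase, had 17.7, 20.9, 2.83 and 4.84 CPM, a log2 fold change of -2.34 (SE 0.33). Arhgap31, a GTPase-activating protein, had 203, 197, 106 and 116 CPM (log2 fold change -0.85, SE 0.10), and Nnt, the mitochondrial transhydrogenase, had 43.9, 42.8, 75 and 72.8 (0.77, SE 0.11). Dusp14 had 38.8, 40.1, 75 and 64.4 CPM, Ephx2 had 6.03, 6.33, 16.6 and 14.9, Papss2 had 4.81, 7.66, 18.2 and 22.2, and Akp3, an intestinal alkaline phosphatase, had 1.12, 0.791, 4.47 and 9.24. Some other enterocyte genes among the 100 with the smallest p had higher values in labelled flox without passing the quasi-likelihood test. Examples are Fabp1, given below, and Alpi and Mttp, named after their values were seen. Alpi had 16.2, 14.6, 26.5 and 29.5 CPM, and Mttp had 24.2, 32.3, 77.3 and 45.8. Picked by their small p, they are no test of enterocyte genes as a set. Of the 9 genes from Kcnn2 to Akp3, all but Kcnn2 had an adjusted p = 1 by edgeR. DESeq2, which called more unchanged genes in the simulation, called all 9 of them, with adjusted p from 3.9e-07 for Kcnn2 to 0.0103 for Akp3 and Dusp14.

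Of 327 tested members of the 26 fixed gene lists, 0 passed the quasi-likelihood test over all genes, 11 had an unadjusted p under 0.05, and 0 passed by DESeq2, the likelihood ratio test, the exact test or limma-voom. Adjusted over the list alone, 1 gene passed, Il22 in the list of innate lymphoid cells, with 0.681, 0.643, 5.53 and 3 CPM. Of 25 lists with at least 4 tested members, camera with its preset correlation called 6 by label and fry called 0, with 8 of camera's lists at an unadjusted p under 0.05. With an estimated correlation camera called 0, and each of the 6 had an adjusted p = 0.847. In the simulation this setting also missed the 1 raised list, so its lack of calls decides little about the 6. Without voom weights the cytokine, epithelial and myeloid lists were not called (adjusted p = 0.0865, 0.0865 and 0.3 by camera). Directions below are of labelled flox against labelled wt.

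The list of immediate early and heat shock genes, which cell handling can raise, was higher in labelled flox by camera (19 members tested, adjusted p = 4.64e-06, and adjusted p = 0.847 with an estimated correlation). Whether handling raised it here was not tested. Several heat shock members were highest in the library labelled flox 2. Hspa8 had 2100, 1880, 2380 and 4360 CPM, Hsph1 had 104, 98, 156 and 691, Hsp90aa1 had 390, 394, 466 and 980, and Hspa1a, named after its values were seen, had 35.5, 103, 80.9 and 892. The stress-responsive transcription factor Atf3 had 39.2, 28.7, 55.5 and 48.8. Without the library labelled wt 2 the list had an adjusted p = 0.354 by camera, and without the library labelled flox 2 it was still called (adjusted p = 1.4e-05). The list of resting and central T cell genes was lower in labelled flox (16 members, adjusted p = 0.0193, and 0.847 as adjusted p with an estimated correlation). In it, Il7r, the interleukin 7 receptor, had 286, 436, 239 and 251 CPM, Igfbp4 had 107, 101, 86.9 and 57.2, Foxp1 had 296, 266, 251 and 249, and Satb1 had 240, 310, 239 and 237. Its adjusted p was 0.391 without the library labelled wt 1 and 0.295 without flox 2. Cytokines and ligands of the TNF family were higher (23 members, adjusted p = 0.0444, and 0.847 as adjusted p with an estimated correlation). Among them Ifng had 4.28, 6.08, 5.37 and 20.7 CPM, Areg had 319, 259, 440 and 310, and Lta had 31.1, 38.2, 35.9 and 62.8. The adjusted p of this list was 0.88 without the library labelled wt 2 and 0.754 without flox 2.

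The other 3 lists called by camera hold markers of cells that the sort should have removed. B cell and plasma cell genes were higher in labelled flox (19 members, adjusted p = 0.00746, and adjusted p = 0.847 with an estimated correlation), as were epithelial genes (19 members, with the same pair of values) and myeloid and dendritic cell genes (17 members, adjusted p = 0.0467, and 0.847 as adjusted p with an estimated correlation). Among B cell genes, H2-Eb1, a class II histocompatibility gene, had 13.1, 20.9, 38.5 and 18.9 CPM, Bank1 had 2.87, 4.75, 5.41 and 7.16, and Ebf1 had 0.681, 0.643, 2.46 and 0.871. Without the library labelled flox 1 the direction of the B cell list turned (adjusted p = 0.636), and without wt 1 its adjusted p was 0.12. Among epithelial genes, Fabp1, a fatty acid carrier of enterocytes, had 9.53, 13.4, 34.5 and 23 CPM, Lypd8 had 3.01, 19.1, 26.9 and 26.9, Krt19 had 3.01, 15.1, 31.7 and 9.33, and Cldn3 had 1.12, 8.31, 9.95 and 9.19. The library labelled wt 1 was lowest for all 4, and without it the direction of the list turned (adjusted p = 0.105); without flox 1 the adjusted p was 0.148. The macrophage and monocyte genes Lyz2, C1qa and C1qc were also lowest there, with 7.97, 41.2, 66.9 and 42.9 CPM for Lyz2, 0.146, 2.77, 5.37 and 2.51 for C1qa, and 0.438, 3.46, 6.64 and 3.63 for C1qc. Flt3 had 0.924, 1.19, 0.655 and 0.145 CPM. The adjusted p of the myeloid list was 0.843 without wt 1 and 0.785 without flox 1.

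The remaining lists were not called by camera, and 0 of their members passed over all genes by the quasi-likelihood test. The list of core regulatory T cell genes (20 members, adjusted p = 0.151) held Gpr83 at 166, 170, 140 and 141 CPM, Tnfrsf18 at 472, 411, 506 and 520, and Tnfrsf4 at 775, 594, 825 and 802. Effector and suppressive genes (18 members, adjusted p = 0.143) included the cytotoxic protease Gzmb at 184, 375, 457 and 362 CPM, Klrg1 at 114, 66.4, 86.7 and 35.1, Fgl2 at 193, 272, 242 and 286, and Tnfrsf9 at 617, 629, 682 and 772. In the type 17 list (15 members, adjusted p = 0.906), Il6ra had 71.3, 40, 52.9 and 29.3 CPM and Tmem176b 11.6, 6.63, 23.7 and 4.16. In the follicular list (23 members, adjusted p = 0.899), Slamf6 had 304, 342, 254 and 283 CPM, Asap1 had 157, 153, 136 and 140, Il4 had 12.3, 10.1, 13.1 and 16.9, and Sostdc1 had 77.6, 41.7, 81 and 90.3. The lists of type 2 and tissue genes (14 members) and of type 1 genes (17 members) had an adjusted p of 0.129 each by camera. Ptger2 had 120, 111, 124 and 154 CPM and Cish 288, 216, 267 and 371 in the former, and Ccl4 had 7.29, 8.01, 11.7 and 9.33 and Gzmk 1.07, 1.14, 0.287 and 0.725 in the latter. Homing receptors (23 members, adjusted p = 0.906) included the colon-homing receptor Gpr15 at 33.6, 34.1, 27.2 and 24.9 CPM, Itgb7 at 1040, 1040, 1170 and 1140, and Cxcr4 at 195, 105, 204 and 186. Among inhibitory receptors (15 members, adjusted p = 0.499), Lilrb4 had 154, 183, 207 and 200 CPM, Cd274 had 152, 144, 148 and 208, and Cd96 had 270, 492, 396 and 543. For the MAF family (6 members, adjusted p = 0.398), Mafg had 43.8, 16, 38.3 and 16.4 CPM, Mafk had 147, 115, 140 and 133, and Mafa had 0.486, 0.544, 0.614 and 0.484.

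Early response genes of the T cell receptor (16 members, camera adjusted p = 0.106) included Nr4a2 at 461, 307, 581 and 474 CPM and Rel at 183, 118, 205 and 219. Cell cycle genes (25 members, adjusted p = 0.398) included Mcm3 at 84.6, 94.1, 72 and 84.2 CPM, Aurkb at 4.96, 4.5, 3.65 and 2.85, Cenpe at 6.56, 7.66, 5.61 and 4.98, and Ube2c at 2.24, 1.43, 2.54 and 2.76. For interferon response genes (20 members, adjusted p = 0.116), Isg15 had 48.7, 41.6, 53.1 and 66.3 CPM, Irf1 had 277, 267, 329 and 297, Rsad2 had 6.71, 8.55, 11.2 and 10.3, and Ifi44 had 0.292, 0.989, 2.29 and 2.66. CD8 T and natural killer cell genes (9 members, adjusted p = 0.752) included Cd8a at 8.56, 5.19, 11 and 9.19 CPM, Prf1 at 10.7, 16.4, 11.3 and 11.4, Fcer1g at 0.632, 0.841, 2.13 and 4.93, and Tyrobp at 1.85, 3.02, 2.46 and 0.484. A more abundant member, the protease Gzma, named after its values were seen, had 48.5, 420, 221 and 210 CPM. In the list of conventional CD4 T cell genes (11 members, adjusted p = 0.901), Themis had 72.3, 62.7, 76.3 and 97.8 CPM. Kit, in the list of innate lymphoid cells (10 members, adjusted p = 0.906), had 14.9, 109, 26.7 and 13.1 CPM. Stromal and endothelial genes (7 members, adjusted p = 0.944) included Pecam1 at 74.3, 82.7, 77.4 and 63.9 CPM, Pdgfrb at 0.146, 1.29, 0.778 and 2.22, Kdr at 0.389, 1.58, 0.041 and 0.871, and Acta2 at 0.632, 0.198, 1.39 and 0.145. The list of red cell genes had 1 tested member, Alas2, at 1.51, 0.989, 3.81 and 0.145 CPM, and was not tested as a list.

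Genes near the modified loci were also compared by label. Of 9 tested genes near Maf on chromosome 8 (adjusted p = 0.962 by camera), Atmin had 79.5, 87.6, 75.3 and 81.7 CPM, Wwox had 6.86, 7.52, 5.86 and 6.77, and Cmip had 217, 257, 252 and 245. Near Foxp3 on the X chromosome (7 members, adjusted p = 0.828), Syp had 60.7, 69.6, 44.1 and 52.1 CPM, Wdr45 had 49.7, 49, 40.7 and 42.1, Ppp1r3f had 38.1, 36.7, 47.6 and 38.2, and Prickle3 had 49.4, 43.4, 46.4 and 54.6. All 4 libraries held Y-linked transcripts (4 tested members of the sex-linked list, adjusted p = 0.706), with Ddx3y at 295, 224, 292 and 295 CPM, Uty at 81.6, 63.7, 79.7 and 77.4, Kdm5d at 44.4, 63.1, 51 and 50.8, and Eif2s3y at 127, 127, 119 and 131.

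The normalized values that the authors deposited held the same pattern of Maf, at 3177, 42.2, 2623 and 15.62. Over 10602 genes shared with the test, the log2 ratio of the labelled groups' means in that table and the fitted log2 fold change had a Pearson correlation of 0.999 across genes, and the log2 ratio of Maf was -0.29. In the same table Il10 had 9129, 525.2, 8290 and 573.5 and Foxp3 had 1996, 2221, 1959 and 2215.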

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

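In this part the summed counts of Gnpda1 and Gm8615 were chosen after the data had been seen. The 1 called gene, Gm8615, was also called with RLE or upper-quartile factors, library totals only, a filter of CPM above 1, a minimum fold of 1.5, no robust estimation, or without immunoglobulin, hemoglobin and mitochondrial genes, which took out 1 tested gene. DESeq2 called 12 genes (9 higher and 3 lower in labelled flox), the likelihood ratio test 12 (8 and 4), the exact test 6 (4 and 2), and edgeR without a filter 2 (2 and 0). Gm8615 was among the genes called in each of these. Limma-voom called 0 and so did limma on the authors' values plus 1 on the log2 scale, with 262 and 198 genes at an unadjusted p under 0.05. With Gnpda1 and Gm8615 summed the count was 0, by construction, as Gm8615 was no longer tested. Each fit that left out 1 library called 0 genes (a range of 0 to 0, with 0 to 0 higher), where the lone library is assumed to vary like the others and 202 to 430 genes had an unadjusted p under 0.05. The cause of the other differences was not tested. No fit could be made without both libraries whose label was at odds with Maf, since 1 library per label remained. Scaling by library totals moved the median log2 fold change by -0.025.

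The deviations of same-numbered libraries from their label's mean had a correlation of 0.264. Same-numbered libraries also shared the Maf level, at 149 and 122 CPM for number 1 and 1.98 and 0.725 for number 2. A replicate block therefore takes out the difference in Maf level too and cannot be read as a pairing by batch alone. With the replicate block 1 gene was called, and Il21 (0.18) and Alas2 (-0.31) had the opposite sign of log2 fold change. By limma-voom Il10 (0.02), Il21 (0.63) and Alas2 (-0.49) did. None of these values passed the threshold (adjusted p = 1 by edgeR or limma). Under other settings that kept all libraries, the remaining named genes kept their sign, and 10 passed under at least 1 of them.

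The log2 fold change of Maf by label ranged from -6.69 to 4.95 with 1 library left out. For 31 other named genes the sign depended on the library left out, with ranges of log2 fold change as follows: Acta2 -1.48 to 1.94, Alas2 -3.05 to 1.61, Bcl6 -0.32 to 0.90, Ccr6 -0.51 to 0.00, Cd96 -0.07 to 0.80, Cmip -0.05 to 0.20, Ctla4 -0.30 to 0.74, Cxcr5 -0.58 to 1.04, Ddx3y 0.00 to 0.39, Eif2s3y -0.09 to 0.05, Fgl2 -0.04 to 0.46, Foxp3 -0.11 to 0.07, Gata3 -0.23 to 0.66, Icos -0.11 to 0.84, Il10 -3.08 to 3.07, Il17a -1.15 to 2.21, Il21 -3.32 to 4.46, Il2ra -0.25 to 0.09, Il6ra -0.93 to 0.04, Kdm5d -0.31 to 0.20, Kdr -4.41 to 0.21, Kit -2.45 to 0.42, Mafa -0.09 to 0.25, Mafg -0.87 to 0.78, Mafk -0.10 to 0.25, Pdcd1 -0.36 to 0.84, Prdm1 -0.41 to 0.20, Prf1 -0.53 to 0.09, Tmem176b -1.13 to 1.38, Tyrobp -2.31 to 0.02 and Uty -0.05 to 0.30.

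Camera called 6 lists, 0 with an estimated correlation, 0 by fry and 3 without voom weights. With the replicate block it called 8 lists, which hold 5 of the 6, and the myeloid list had an adjusted p = 0.144. With 1 library left out it called 4 to 10 lists. The adjusted p of the B cell list ranged from 8.92e-12 to 0.636 and that of the epithelial list from 9.47e-13 to 0.148, and both turned direction in 1 of these fits. The correlation between the libraries labelled wt 1 and flox 1 was 0.724 over the 500 most variable genes, against 0.976 over all tested genes, since those genes were chosen for their spread. Counts limit the ratios of Maf, Il21 and Gm8615, whose lowest libraries held 15, 7 and 1 counts.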

Other observations

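All tests in this part were chosen after the result they bear on was seen, except the recomputed pseudo-counts and the count over other groupings.

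The 60 genes with the largest spread of log2 CPM over the 4 libraries were listed, among genes with a mean log2 CPM of at least 3 and without predicted genes, pseudogenes and receptor segments. Some are also members of the fixed lists. Most went with the number of the library. Both libraries numbered 1 lay above both numbered 2 for 35 of them, the opposite held for 12, and 4 were higher and 3 lower in both libraries labelled flox. After Maf, the first of these was Gbp2b, an interferon-induced guanylate-binding protein, at 130, 2.27, 116 and 2.47 CPM in the libraries labelled wt 1, wt 2, flox 1 and flox 2. The chemokine Ccl20 had 86.4, 5.93, 85.4 and 5.32 CPM, and the chemokine receptor Ccr2 had 165, 14.7, 159 and 9.87. The matrix protein gene Matn2 had 59.8, 3.91, 38 and 0.58, and the B cell coactivator Pou2af1 had 32.8, 6.18, 33.3 and 3.82. In the other direction lay the granule gene Nkg7, at 12.7, 101, 31 and 118 CPM, and Cd7, at 16.3, 142, 34.8 and 93.1. The limit on the mean and the genes left out matter here, since Kcnn2 and Gm8615, which separated by label, do not enter this list. These genes were picked for their spread, so no test was made of them.

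Single libraries also stood apart. Hspa1b had 71.2, 199, 151 and 1590 CPM, Prox1 had 4.76, 8.45, 5.86 and 33.1, and Tmem87a had 69.9, 73.1, 78.7 and 12.3, each with the library labelled flox 2 farthest from the rest. The antimicrobial lectin Reg3b of gut epithelium had 1.41, 82, 30.9 and 110 CPM, lowest in the library labelled wt 1. Ly6e had 2450, 2560, 1370 and 381 CPM.

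Maf was high in the libraries labelled wt 1 and flox 1 and low in wt 2 and flox 2. A difference in depth is excluded, since gene totals differed by at most 1.27 times. Incomplete deletion in the library labelled flox 1 alone is excluded too, since the library labelled wt 2 held 0.0132 times the Maf level of wt 1. The table of normalized values bears on the authors' own grouping. Its values were recovered with the libraries grouped by number (100% within 1e-06), whereas the labelled groups left a median relative error of 4.8e-05 (3.2% within 1e-06). This argues against the labelled groups as the grouping behind these values. It does not tell which group was wild type, or whether the column names or that grouping are in error. An exchange of labels between wt 2 and flox 1 is a candidate explanation that needs 1 library out of place in each group, and the Maf level of the library labelled flox 1 was 0.816 times that of wt 1. The replicate field of the labels, which puts wt 1 with wt 2 and flox 1 with flox 2, is what such an exchange would leave if that field were right. Age and backcross generation were the same for every library and cannot tell the animals apart. The labels hold no other record of the animals. Gm8615 and Kcnn2, picked by their small p, parted by label, with 1, 1, 440 and 454 counts and 0, 0, 229 and 176. Whether such genes tell the animals apart was not tested, so the exchange remains a hypothesis. A biological cause of low Maf in a wild-type library was not tested.

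By label 1 gene passed the threshold, and of the other groupings the one by library number had the highest count, 236 genes. As many as 1 gene were called in 2 of the 3 groupings, the labelled one included, and 3 groupings cannot give a share under 0.05. The higher count goes with the library number, which coincides with the Maf level, and not with the labelled genotype.

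A rise of Gm8615 alone is argued against. With Gnpda1 at its level in labelled wt it would give the summed counts of both genes a log2 fold change of 0.48, and the observed -0.23 (SE 0.20, adjusted p = 1 by edgeR's quasi-likelihood test) lay 3.5 SE below that. Gnpda1 alone had -1.11 (SE 0.21) and did not pass that test. This fall was seen before the comparison was made, so the comparison largely restates it. The value of 0.48 was taken as free of error. A candidate explanation is that reads of 1 gene were divided differently between both. Separate changes of both genes in opposite directions were not excluded, and a sequence variant was not tested because reads were not used here.

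Several genes with small p by label lie on chromosome 18. The set held the 100 genes with the smallest p among the 12382 with a position. Nnt had no position here and did not enter it. Of these 100 genes, 8 lay between 33.2 and 45.5 Mb of chromosome 18, among them Gnpda1, Sh3rf2, Kcnn2 and Prelid2. Prelid2, named after its values were seen, had 8.65, 14.1, 28.3 and 34.4 CPM. No window of 20 Mb on any chromosome held more, where random sets had a median of 5 and a 95th percentile of 7 (permutation p = 0.036); in windows of 10 Mb the highest count was 7 (permutation p = 0.018). Reads may be divided between Gnpda1 and Gm8615. Without both, the highest counts were 7 in 20 Mb (permutation p = 0.14) and 6 in 10 Mb (permutation p = 0.089). Leaving out other genes of the window was not tried, so this does not single out Gnpda1. Thus 1 inherited segment that differs between the mice is neither supported nor excluded by these counts. Over the whole set, 41 genes had another of the 100 within 5 Mb (median of random sets 42), a count that a single segment would move little. None of the set (0) lay within 20 Mb of Maf (median of random sets 2), which decides nothing about DNA flanking the floxed allele while the labels are at odds with Maf.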
